A study of Mus musculus with 7 samples.

How the data were processed

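Whole retinas of C57BL/6 mice were collected 2 days after optic nerve crush, per the labels' protocols, and their RNA was selected for poly(A) tails, made into libraries with a kit that does not mark strand, and sequenced as paired reads of 150 bases. The deposited table holds raw counts per gene symbol, whole numbers that were not normalized, per the file headers. The submitters' processing notes name the mouse genome build GRCm39 (mm39). The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping genes and of near-identical copies may be split in unknown ways. The labels' protocols state that a synthetic spike-in was added, but no row among those analysed carries a spike-in name, so spike-in scaling was not used. No genomic coordinates are printed, because the annotation used for transcript GC content and length was of another build.

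The labels name 4 control AAV2 and 3 Tppp3 AAV2 samples, whereas the treatment protocol in the labels gives 4 Tppp3 and 3 control retinas. The sample labels were followed. A column was used only where its name matched the title of a sample. That gave 6 libraries, replicates 1, 2 and 3 of each group. The fourth control sample had no matching column and was not analysed here, and 1 column that matched no sample, and whose name gives it as the fourth Tppp3 library, was not used in any step. All fits planned for 7 libraries were therefore made on 6. Each sample title carries a number of its own, which the labels do not explain, and Y-linked counts differed within each group, so that each group held libraries of different animals. Whether every library came from another animal is not stated.

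Library totals ranged from 10961443 to 21843892 counts, and every control library was shallower than every Tppp3 library. Chi-square statistics of raw counts per gene lay between 4.05 and 13.8 for pairs within a group, far above sampling noise, so no pair was a single library deposited under both names. Of 25655 genes, 14750 passed edgeR's filter on expression by group. Libraries were scaled by TMM, dispersions and quasi-likelihood fits were made with the robust option, and Tppp3 AAV2 was tested against control AAV2 with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 11.9%. Standard errors were obtained from the fold change and the F statistic. Group levels are given as TMM-scaled CPM, counts relative to the effective library size, computed here. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

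Before the data were examined, 43 gene lists were fixed for retinal cell types, cells from outside the retina, injury and stress pathways, and library quality. They were compared with all other genes by limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and the 41 lists with at least 5 tested members were adjusted together. Estimated correlations and limma's fry served as alternatives. Of 742 listed symbols, 8 had no row in the table, and 42 rows carry a numbered symbol that was not matched to a list. The rule for named genes was also fixed in advance. It took Tppp3 first, then up to 12 genes of smallest p in each direction among those past the threshold with a mean of at least 1 CPM and no overlap between groups. Where fewer passed, genes of smallest p that failed filled up to 5 per direction. It then took the 4 members of smallest p of each called list, and of the ganglion cell, regeneration-associated, microtubule, BMP, cytokine, reactive glia and microglia lists in any case. Predicted genes and pseudogenes were counted but not named. Some genes that the rule selects are not reported here.

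The procedure was tested on simulated counts with the means, dispersions and library sizes of this comparison, with 200 genes drawn to change. Among 14628 genes fitted, it recovered 61.2% of those changed 1.5-fold, 79.2% of those changed 2-fold, 90.0% of those changed 3-fold and 95.9% of those changed 4-fold, and called 21 of 14432 unchanged genes. These were 11.6% of its 181 calls, above the nominal share of the 0.05 threshold. In a second simulation, a list shifted by 0.3 on the log2 scale was called and 0 other lists were. Genes were drawn independently of each other, so the simulated lists had no correlation between members. The result therefore cannot show how often the preset correlation calls real lists falsely. With 200 changed genes the adjusted threshold is also easier to pass than where few genes change. The shares recovered may therefore overstate what the real comparison could find.

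Other settings, also chosen in advance, were DESeq2's size factors, DESeq2's Wald test, limma's voom with quality weights, no low-count filter, a mean of at least 1 CPM, leaving out each library, the replicate number as a block, the other list tests and a threshold of 0.10. Settings added after seeing the data were a covariate for sex read from Y-linked counts, a covariate for the mean of the pigment epithelium list, a correction for GC content and length, and thinning of all libraries to the smallest total. The correction removed each library's local trend on transcript GC content and length, fitted without ribosomal protein and oxidative phosphorylation genes. Of the tested symbols, 97.9% were matched to a transcript, including 100% of the ribosomal protein list and 95.9% of the oxidative phosphorylation list.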

Results

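Poly(A)-selected RNA of whole mouse retina was sequenced 2 days after crush of the optic nerve, an injury to the axons of retinal ganglion cells. The retinas had been treated with AAV2, an adeno-associated viral vector often used to reach these cells, that carried either Tppp3 or a control construct. Tppp3 encodes a tubulin polymerization-promoting protein. The comparison asked which transcripts changed in the injured retina with Tppp3 overexpression, given the submitters' interest in axon regrowth and ganglion cell survival. It rested on 3 control AAV2 libraries and 3 Tppp3 AAV2 libraries. Control replicates 1, 2 and 3 held 11325596, 16218074 and 10961443 gene counts, and Tppp3 replicates 1, 2 and 3 held 19961359, 21843892 and 21391585, so that every Tppp3 library was deeper than every control library. Of the 25655 genes in the count table, 14750 had enough counts to be tested.

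Tppp3 itself was higher in each of the 3 Tppp3 AAV2 libraries than in any control library. It averaged 23.002 ± 4.68 CPM (counts scaled to the effective library size) in the controls and 44.0 ± 8.81 with the vector (SD, n = 3 per group), a 1.91-fold difference in the fit. The 3 control libraries held 18.7, 22.2 and 28.02 CPM, and the 3 vector libraries held 53.7, 36.5 and 41.8. The log2 fold change was 0.94 ± 0.20 (SE). In edgeR's quasi-likelihood test its unadjusted p was 0.0031 and its adjusted p over all genes 0.639. DESeq2's Wald test gave an adjusted p of 1.3e-05, and the adjusted p ranged from 1.3e-05 to 0.907 over all alternatives. A two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The groups did not overlap in 13.9% of all tested genes, where 10% is the share by chance. Tppp3 stood at rank 60 by p in edgeR's test. Reads from the native gene and from the vector were not separated.

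**Figure D1:**
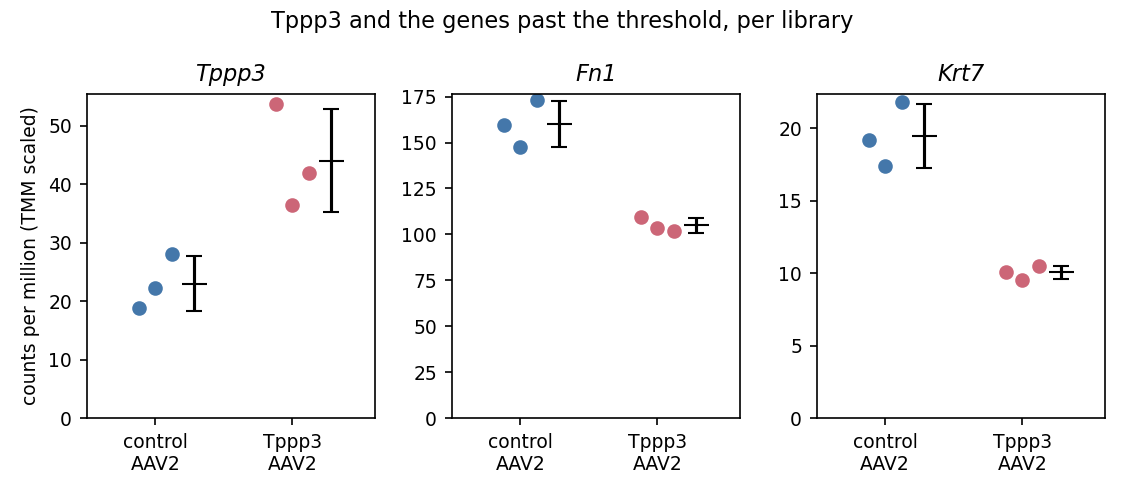
TMM-scaled CPM of Tppp3, Fn1 and Krt7 in each library (coloured points), with the mean and SD of each group of 3 libraries in black; each vertical axis starts at 0. Tppp3 averaged 23.002 in the controls and 44.0 with the vector, and Fn1 fell from 160.1 to 104.9 and Krt7 from 19.5 to 10.1.

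Few transcripts passed the test. Fn1, which encodes the extracellular matrix protein fibronectin, and Krt7, which encodes an epithelial keratin, were lower with Tppp3 AAV2, and no gene was higher at an adjusted p under 0.05. Fn1 averaged 160.1 ± 12.8 CPM in the controls and 104.9 ± 4.16 with Tppp3 AAV2 (SD, n = 3 per group). Its log2 fold change was -0.61 ± 0.063 (SE), with an edgeR adjusted p of 0.0138. Krt7 averaged 19.5 ± 2.21 and 10.1 ± 0.468 CPM, with a log2 fold change of -0.95 ± 0.11 and an edgeR adjusted p of 0.0321. At an unadjusted p under 0.05 the same test gave 542 genes higher and 524 lower. DESeq2's Wald test placed 2 genes higher, Tppp3 and Spred1, and 12 lower past the threshold, and limma's voom with quality weights placed 0 in each direction.

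Both calls were lost when some single libraries were left out, while over all alternatives the log2 fold change stayed between -0.66 and -0.55 for Fn1 and between -1.03 and -0.86 for Krt7. The adjusted p of Fn1 rose to 0.112 without control replicate 3, 0.0642 without Tppp3 replicate 2 and 0.148 without Tppp3 replicate 3, within a range of 7.9e-12 to 0.184 over all alternatives. For Krt7 it rose to 0.0625, 0.0780 and 0.303 without control replicates 1, 2 and 3, and to 0.168, 0.121 and 0.155 without Tppp3 replicates 1, 2 and 3, within a range of 1.3e-05 to 0.303. With sex as a covariate, read from Y-linked counts, the adjusted p was 0.0885 for Fn1 and 0.128 for Krt7, and after thinning to equal depth that of Krt7 was 0.0571. The raw counts of Krt7 were 217, 283 and 241 in the controls and 199, 212 and 221 in the deeper Tppp3 libraries. Those of Fn1 were 1806, 2401 and 1915 in the controls and 2158, 2289 and 2145 in the Tppp3 libraries.

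The genes next in order of p did not pass the threshold. On the lower side they were the epithelial genes Itgb4 (log2 fold change -0.96, adjusted p = 0.0650 in edgeR's test) and Krt8 (-0.79, adjusted p = 0.115), and the galectin gene Lgals1 (-0.70, adjusted p = 0.115). On the higher side, Spred1, an inhibitor of Ras and MAP kinase signalling, averaged 80.1 ± 2.20 CPM in the controls and 101.4 ± 4.25 with the vector (SD, n = 3 per group; log2 fold change 0.34, edgeR adjusted p = 0.115). Itgb4, Krt8, Lgals1 and Spred1 passed with DESeq2's Wald test, at adjusted p of 0.00107, 0.00132, 9.9e-05 and 0.00845. Over all alternatives, their adjusted p ranged up to 0.766 for Itgb4 and 0.894 for Krt8, Lgals1 and Spred1. Nbeal1 had a log2 fold change of 0.27 (adjusted p = 0.606), Neurod4, a neuronal transcription factor, 0.22 (adjusted p = 0.624), and Med13, a part of the Mediator complex, 0.23 (adjusted p = 0.639) in the same edgeR test. Commd1b was nearly absent from the controls, at 0.147 ± 0.255 CPM, and at 2.98 ± 1.08 with the vector (SD, n = 3 per group; edgeR adjusted p = 0.606). Its level is uncertain, since how the authors' counting treated reads shared with its relative Commd1 is not known.

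Gene groups fixed in advance were then compared with all other genes by limma's camera with a preset correlation of 0.01. Of the 41 groups tested, 8 stood apart. Ribosomal protein, oxidative phosphorylation, cholesterol synthesis and proliferation genes lay lower with Tppp3 AAV2, and pigment epithelium, heat shock, hypoxia and glycolysis, and microtubule genes lay higher. None of the 8 calls held with an estimated correlation, which gave an adjusted p of 0.877 for each. No member of these 8 groups passed the threshold over all genes.

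**Figure D2:**
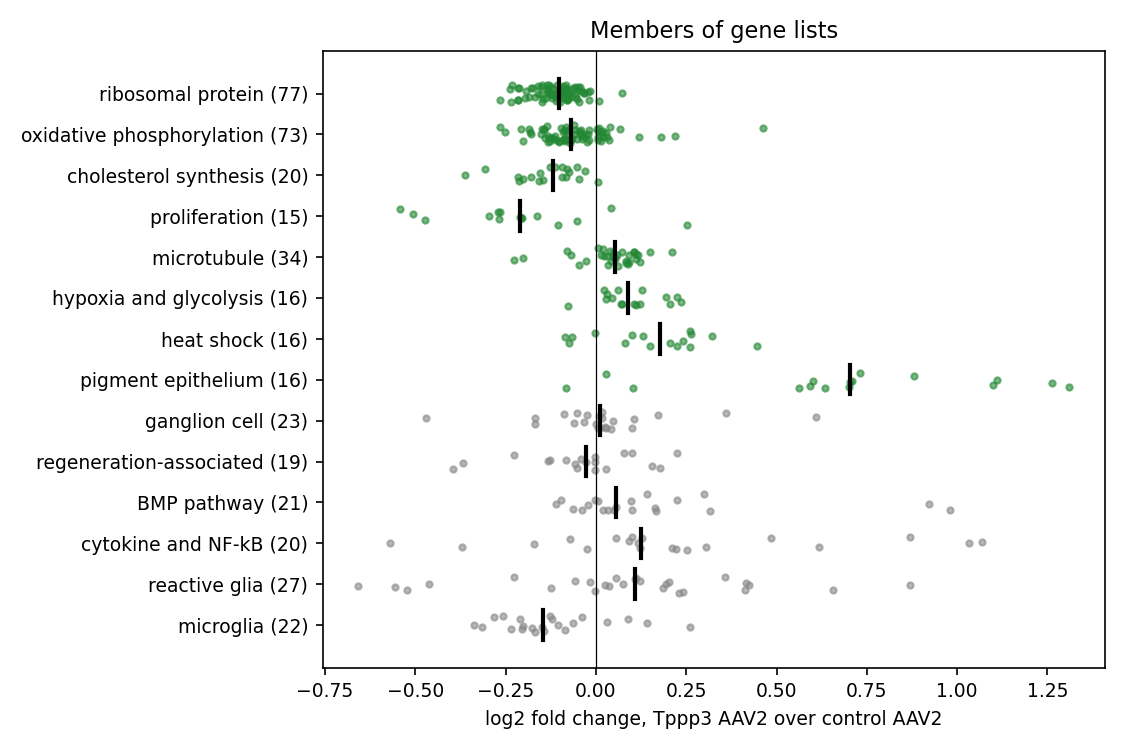
Log2 fold change of each tested member (points) of 14 gene lists, Tppp3 AAV2 over control AAV2, with the median of each list as a black bar and the number of members in brackets; vertical scatter of points carries no value. The upper 8 lists (green) were called by camera with a preset correlation, and the lower 6 (grey) were not; medians ranged from -0.21 for proliferation genes to 0.70 for pigment epithelium genes.

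Ribosomal protein genes, which build the cytosolic ribosome, shifted by a small amount in nearly every member. Of 77 members, 75 had a negative fold change, with a median log2 fold change of -0.10 (camera adjusted p = 8.3e-16, and adjusted p = 0.877 with an estimated correlation). After a correction for GC content and transcript length the ribosomal protein median was -0.047 and its camera adjusted p 2.3e-04, and over all alternatives that p ranged from 1.8e-22 to 0.877. Rplp0 had a log2 fold change of -0.26, Rps19 of -0.23 and Rpl19 of -0.22. Adjusted over the list alone, 11 members passed, and 0 passed over all genes tested in edgeR. Nuclear genes of oxidative phosphorylation, which supply the mitochondrial respiratory chain, were negative in 54 of 73 members, with a median of -0.069 (camera adjusted p = 7.2e-05, and adjusted p = 0.877 with an estimated correlation). Ndufb8 stood at -0.19, Ndufa7 at -0.27, Atp5pb at -0.14 and Ndufb4 at -0.21. After the same correction the oxidative phosphorylation median was -0.0093 and its camera adjusted p 0.616, within a range of 1.4e-05 to 0.877 over all alternatives. Uncorrected, the median was -0.042 without control replicate 1. The 13 protein genes of the mitochondrial genome had a median of 0.0070 and were not called.

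Cholesterol synthesis genes were negative in 19 of 20 members, with a median log2 fold change of -0.12 (camera adjusted p = 6.0e-04, and adjusted p = 0.877 with an estimated correlation). The sterol synthesis enzyme genes Nsdhl and Mvd stood at -0.36 and -0.21, and Acat2 at -0.21. The call was lost without control replicate 1 (adjusted p = 0.0923) and without Tppp3 replicate 2 (adjusted p = 0.164), in a range of 5.1e-09 to 0.899. The median was -0.18 without control replicate 2, -0.19 without Tppp3 replicate 1 and -0.053 without Tppp3 replicate 2. Proliferation genes were negative in 13 of 15 members, with a median of -0.21 (camera adjusted p = 0.0146, and adjusted p = 0.877 with an estimated correlation). The replication licensing genes Mcm2 and Mcm5 stood at -0.47 and -0.21, Ccna2 at -0.21 and Rrm2 at -0.54, and Mcm2 alone passed when adjusted over the list alone. With single libraries left out, Mcm5 ranged from -0.26 to -0.14, Ccna2 from -0.30 to -0.12 and Rrm2 from -0.79 to -0.16. The call was lost without control replicate 3 (adjusted p = 0.274), Tppp3 replicate 2 (adjusted p = 0.137) or Tppp3 replicate 3 (adjusted p = 0.103), and with the pigment epithelium level as a covariate (adjusted p = 0.199), in a range of 3.1e-04 to 0.899. The median was -0.33 and -0.13 without control replicates 1 and 3, and -0.43 and -0.093 without Tppp3 replicates 1 and 3.

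Heat shock and chaperone genes were positive in 12 of 16 members, with a median log2 fold change of 0.18 (camera adjusted p = 0.00262, and adjusted p = 0.877 with an estimated correlation). The cochaperone genes Chordc1, Dnajb1, Dnaja1 and Bag3 had log2 fold changes of 0.32, 0.26, 0.23 and 0.44, and the first 3 of them passed when adjusted over the list alone. Dnaja1 ranged from 0.14 to 0.28 with single libraries left out. Without Tppp3 replicate 1 the median was 0.071 and the camera adjusted p 0.0515, in a range of 1.9e-04 to 0.887. Hypoxia and glycolysis genes were positive in 15 of 16 members, with a median of 0.089 (camera adjusted p = 0.0133, and adjusted p = 0.877 with an estimated correlation). The angiogenic factor Vegfa stood at 0.19, the glucose transporter Slc2a1 at 0.21, P4ha1 at 0.23 and Pfkfb3 at 0.12. With single libraries left out, Slc2a1 ranged from 0.12 to 0.25, P4ha1 from 0.14 to 0.28 and Pfkfb3 from 0.056 to 0.16. This call was lost without control replicate 1 (adjusted p = 0.184), control replicate 2 (adjusted p = 0.263) or Tppp3 replicate 3 (adjusted p = 0.0803), in a range of 5.2e-04 to 0.899. The median was 0.036, 0.056 and 0.15 without control replicates 1, 2 and 3.

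Tubulins and microtubule-associated genes, the class to which the Tppp3 product is related, were positive in 28 of 34 members. Their median log2 fold change was 0.053 (camera adjusted p = 0.0133, and adjusted p = 0.877 with an estimated correlation). Map6, whose product stabilises microtubules, stood at 0.15, the kinesin gene Kif5b at 0.11, and the tubulin genes Tubb5 and Tubb4a at 0.12 and 0.092. Tubb5 ranged from 0.062 to 0.15 with single libraries left out. The call was lost without control replicate 1 (adjusted p = 0.152) and without Tppp3 replicate 1 (median 0.035, adjusted p = 0.0764), in a range of 0.00125 to 0.877.

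Pigment epithelium and pigment cell markers had the largest median among the called lists, 0.70, with 15 of 16 members positive (camera adjusted p = 0.00606, and adjusted p = 0.877 with an estimated correlation). The pigment synthesis genes Slc45a2, Pmel, Tyr and Tyrp1 had log2 fold changes of 1.26, 1.11, 1.31 and 1.10. With single libraries left out they ranged from 0.75 to 1.79 for Slc45a2, 0.64 to 2.67 for Pmel, 0.75 to 3.61 for Tyr and 0.51 to 3.02 for Tyrp1. The level differed between libraries within each group. The list mean lay 1.00 above the average of the 6 libraries in control replicate 1 and 1.00 above it in Tppp3 replicates 1 and 3, and at -1.08, -1.37 and -0.55 in control replicates 2 and 3 and Tppp3 replicate 2. The call was lost without control replicate 2 (adjusted p = 0.119), control replicate 3 (adjusted p = 0.160), Tppp3 replicate 1 (adjusted p = 0.0626) or Tppp3 replicate 3 (adjusted p = 0.1003), in a range of 1.4e-07 to 0.899. The median was 2.15, 0.24 and 0.30 without control replicates 1, 2 and 3, and 0.37, 1.14 and 0.45 without Tppp3 replicates 1, 2 and 3.

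The neuronal groups closest to the study's question were not called in the main test. They were measured in whole retina, so a change confined to ganglion cells was not seen apart from other cells. Ganglion cell markers had a median log2 fold change of 0.011 over 23 members (camera adjusted p = 0.825), with 0 members past the threshold over all genes in edgeR. Spp1, the gene of osteopontin, averaged 30.3 ± 2.48 CPM in the controls and 21.9 ± 2.03 with Tppp3 AAV2 (SD, n = 3 per group). Its log2 fold change was -0.47 with an edgeR adjusted p of 0.550, and it alone passed when adjusted over the list alone. Its raw counts were 375, 466 and 322 in the controls and 427, 442 and 505 in the deeper Tppp3 libraries. Eomes, Pou4f1 and Ebf3, transcription factors of ganglion cells, stood at 0.36, -0.17 and 0.10. Regeneration-associated genes had a median of -0.028 over 19 members (camera adjusted p = 0.825), with Tnfrsf12a at -0.37, Basp1 at -0.082, Klf6 at 0.10 and Npy at 0.18. BMP pathway genes had a median of 0.056 over 21 members (camera adjusted p = 0.102). Gdf11 stood at 0.31, the receptor gene Bmpr2 at 0.14, the target gene Id1 at 0.30 and Bmp4 at 0.92. Bmp4 averaged 1.497 ± 0.807 CPM in the controls and 2.83 ± 0.703 with the vector (SD, n = 3 per group), and the groups overlapped; its log2 fold change ranged from 0.65 to 1.39 with single libraries left out, that of Klf6 from 0.029 to 0.17, that of Basp1 from -0.15 to -0.038 and that of Npy from 0.10 to 0.23. The BMP list was called, as higher, without control replicate 1 (camera adjusted p = 0.00764) and without Tppp3 replicate 1 (adjusted p = 0.0215), and the regeneration-associated list, as higher, with the pigment epithelium level as a covariate (adjusted p = 0.00925).

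Inflammatory and glial groups were not called in the main test either. Cytokine and NF-kB genes had a median log2 fold change of 0.12 over 20 members (camera adjusted p = 0.518), with Ptgs2 at -0.57, Il33 at 0.13, Ccl2 at 1.07 and Nlrp3 at 1.03. Ccl2 changed sign to -0.14 without Tppp3 replicate 1, and Nlrp3 fell to 0.51 and Il33 to 0.014 without control replicate 1. Reactive glia genes had a median of 0.11 over 27 members, while camera gave them a downward direction (adjusted p = 0.825). Emp1 stood at -0.66, Tm4sf1 at -0.56, S100a6 at -0.52 and Ptx3 at 0.42, with S100a6 at -0.31 without control replicate 3 and Ptx3 at 0.080 without Tppp3 replicate 1. Microglia markers had a median of -0.15 over 22 members (camera adjusted p = 0.3003), with Sall1 at -0.34, Aif1 at -0.28, Ly86 at -0.20 and C1qb at -0.26. With single libraries left out, Sall1 ranged from -0.61 to -0.11, Aif1 from -0.62 to -0.0078 and C1qb from -0.68 to -0.028, and Ly86 changed sign to 0.015 without Tppp3 replicate 3. The microglia list was called, as lower, with limma's voom (camera adjusted p = 0.00635), without control replicate 1 (adjusted p = 0.00681) and without Tppp3 replicate 2 (adjusted p = 4.1e-04), and as higher with the pigment epithelium covariate (adjusted p = 0.00571). The cytokine list was called, as higher, without Tppp3 replicate 3 (adjusted p = 0.0102), and the reactive glia list, as higher, with that covariate (adjusted p = 0.00425).

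Markers of the other retinal cell types differed little between the groups, and no member of these lists passed over all genes in edgeR. The median log2 fold change was -0.063 over 22 rod genes, -0.014 over 13 cone genes, 0.044 over 18 bipolar cell genes and 0.062 over 17 amacrine cell genes. It was 0.045 over 5 horizontal cell genes, 0.060 over 14 Müller glia genes and -0.099 over 20 vascular genes. Among cells from outside the retina, the median was 0.12 over 8 blood myeloid genes, 0.087 over 5 lymphocyte genes and 0.96 over 7 lens genes. It was -0.35 over 6 genes of corneal epithelium and stroma, where the keratin gene Krt14 passed when adjusted over the list alone, and 0.16 over 4 skeletal muscle genes. It was 0.081 over 7 oligodendrocyte genes and -0.091 over 5 red blood cell genes. None of these lists was called in the main camera test, for which the muscle list was too small. In other settings, rod genes were called as lower without Tppp3 replicate 1 (camera adjusted p = 0.0114), without Tppp3 replicate 3 (adjusted p = 0.0206) and with the pigment epithelium covariate (adjusted p = 3.5e-05). Müller glia genes were called as higher without Tppp3 replicate 1 (adjusted p = 0.0136) and with that covariate (adjusted p = 0.0102), lens genes as higher without control replicate 2 (adjusted p = 0.00380), and muscle genes as higher with no low-count filter (adjusted p = 0.00243) and without control replicate 1 (adjusted p = 0.00764).

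**Figure D3:**
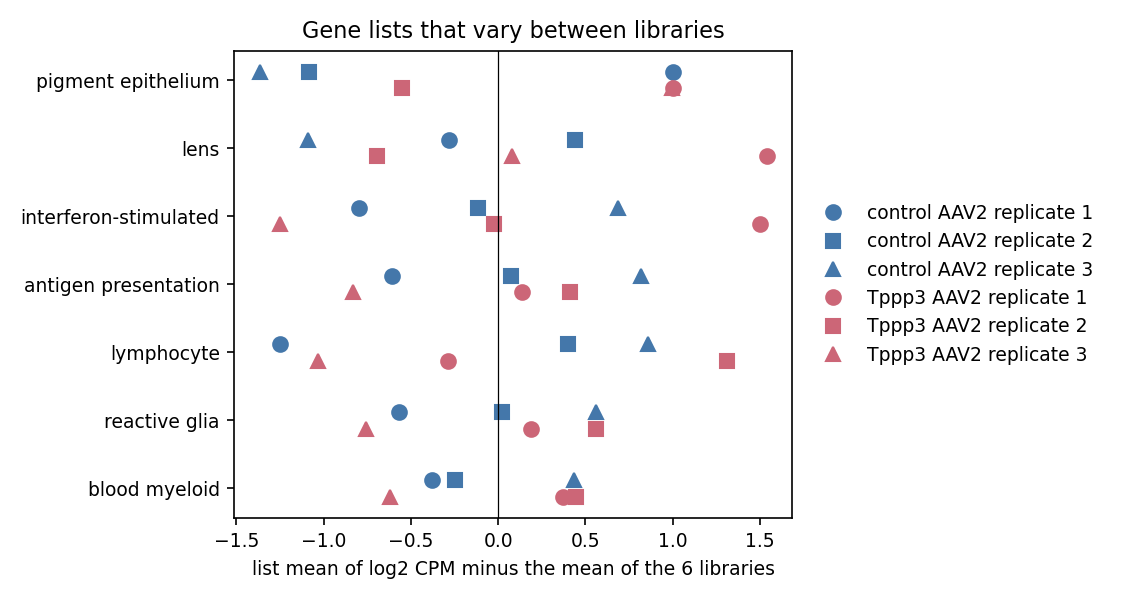
Mean log2 CPM of the members of 7 gene lists in each library, minus the average of the 6 libraries; blue symbols are control AAV2 and red symbols Tppp3 AAV2, with a symbol shape per replicate number. The groups overlap in every list shown; the interferon-stimulated list ranges from -1.25 in Tppp3 replicate 3 to 1.4996 in Tppp3 replicate 1.

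The libraries were alike in their mitochondrial share, but not in the immune and glial transcripts described below. Mitochondrial genes took between 2.91% and 3.16% of all counts. The number of genes with at least 1 count followed the groups. It ranged from 16519 to 16789 in the controls and from 16808 to 16980 with Tppp3 AAV2. Depth follows the groups too, so depth and an effect of the vector cannot be told apart in this number. The share of counts from ribosomal protein genes was higher in every control library than in any Tppp3 library. Y-linked transcripts were abundant in control replicate 1 and Tppp3 replicate 2 and scarce in the other 4, with 2662 and 4956 counts over 4 genes against 10 to 42. The first principal component of log2 CPM held 34.2% of the variance. It placed control replicate 1 and Tppp3 replicate 3 at its lower end, at -25.2 and -21.7, and control replicate 3 at its upper end, at 28.8, so that it did not separate the groups.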

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

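The alternatives with the sex covariate, the pigment epithelium covariate, the GC and length correction and thinning were chosen after seeing the data. Tppp3 was higher with the vector in each of 16 alternatives, with a log2 fold change of 0.76 to 1.10 when single libraries were left out, and it passed the threshold with DESeq2's Wald test (0.94, adjusted p = 1.3e-05). The number of genes higher was 0 in the main analysis, 2 with DESeq2's Wald test, 1 (Cd8a) with the pigment epithelium covariate, and 0 to 2 when single libraries were left out (Ltbp2 and Timp3 without control replicate 1, named after their values were seen). The number lower was 2 in the main analysis, 12 with DESeq2's Wald test, 6 with no low-count filter, 0 with limma's voom with quality weights, 0 with the sex covariate and 1 after thinning. It was 0 to 1 when single libraries were left out, and Fn1 was the gene lower in those with a call. At a threshold of 0.10 the numbers were 0 higher and 3 lower. The cause of these differences was not tested. With the replicate block the number lower was 1, because Krt7 had an adjusted p of 0.0892. Deviations of same-numbered libraries from their group means correlated at -0.048, 0.054 and -0.29, and not every library correlated best with its own number. They gave no sign that the numbers pair the samples, but 3 libraries per group cannot exclude it. The number of gene lists called was 8 in the main analysis, 7 to 9 when single libraries were left out, 10 with limma's voom, 9 with no low-count filter, 12 with the pigment epithelium covariate, 7 after the GC and length correction, 0 with an estimated correlation and 0 with fry, which allow for correlation between the members of a list. With the pigment epithelium covariate the median of that list was -0.036, as follows from its construction, and Aif1, Ly86 and C1qb reversed to 0.37, 0.24 and 0.093. With single libraries left out, Ccl2 ranged from -0.14 (without Tppp3 replicate 1) to 1.57, and Ly86 from -0.46 to 0.015 (without Tppp3 replicate 3). Of 1049 comparisons over the 66 other genes that the naming rule selects, 1022 kept direction and side of the threshold, 15 lost and 7 gained the call, and 5 reversed. Scaling on spike-ins was not run because no row used here is a spike-in. With these library sizes and 3 libraries per group, the simulation recovered 61.2% of 1.5-fold changes. It held 200 changed genes, drawn independently, and made 181 calls, while the real comparison made 2. That share may therefore overstate what could be found here. Other depths were not tested.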

Other observations

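Immune and glial transcripts varied widely between retinas of the same group. Interferon-stimulated genes had a median log2 fold change of 0.42 with 28 of 30 members positive, but the list was not called in the main test (camera adjusted p = 0.474), and Tppp3 replicates 1 and 3 were its highest and lowest libraries, at 1.4996 and -1.25 from the average of the 6. The list was called as higher without control replicate 3 (adjusted p = 0.0299) and without Tppp3 replicate 3 (adjusted p = 1.1e-06), and as lower without Tppp3 replicate 1 (adjusted p = 0.00272). The chemokine gene Cxcl10 had 391 counts in Tppp3 replicate 1 and 41 in Tppp3 replicate 3, and the ubiquitin-like modifier gene Isg15 had 398 and 53. Reactive glia genes were lowest in control replicate 1 and Tppp3 replicate 3, at -0.57 and -0.76, and highest in control replicate 3 and Tppp3 replicate 2, at 0.56 and 0.56. The acute-phase gene Lcn2 had 10.3 and 8.83 CPM in the first pair and 68.1 and 97.6 in the second, and the injury-induced endothelin gene Edn2 18.1 and 11.01 against 63.1 and 73.2. The 5 lymphocyte genes were lowest in the same first pair, at -1.25 and -1.03, and highest in Tppp3 replicate 2, at 1.31. Antigen presentation genes ranged from -0.83 to 0.82. A two-sided exact permutation test between the groups gave p = 0.9, 1.0, 1.0 and 0.8 for the interferon, reactive glia, lymphocyte and antigen presentation lists, where 0.1 is the smallest value possible. These genes were singled out after their values were seen.

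Among the lists not described above, none was called in the main test. The median log2 fold change was 0.034 over 20 genes of the integrated stress and unfolded protein responses, -0.0085 over 19 p53 and apoptosis genes, 0.056 over 14 growth-inhibitory genes and 0.041 over 17 trophic factor genes. It was 0.049 over 18 complement genes, 0.0017 over 17 immediate-early genes, 0.028 over 23 synaptic genes and 0.067 over 12 motile cilium genes. The median was -0.018 over 22 matrix and wound genes, which include Fn1, 0.057 over 16 clock genes, -0.025 over 25 histone genes and -0.18 over the 20 antigen presentation genes. In other settings, antigen presentation genes were called as lower with limma's voom (camera adjusted p = 0.0277), without control replicate 1 (adjusted p = 0.00900) and without Tppp3 replicate 2 (adjusted p = 0.00871). Complement genes were called as higher with the pigment epithelium covariate (adjusted p = 3.5e-05), and synaptic genes as higher without Tppp3 replicate 2 (adjusted p = 0.02004). The sex-linked list, with 2 tested genes, was too small for the test. The p53 and matrix lists had a mean of the other sign than their median, and camera gave the lymphocyte list a downward direction against a median of 0.087. Fry's test for change in either direction gave unadjusted p of 0.0028 for the matrix list and 0.026 for motile cilium genes. One of 2 table rows for the mitochondrial transhydrogenase gene, Nnt_2, had 0 counts in Tppp3 replicate 3 and 79 and 107 in Tppp3 replicates 1 and 2. It varied in the controls too, at 6.19, 4.92 and 12.6 CPM in control replicates 1, 2 and 3. The other row, Nnt_1, was lowest in control replicate 3, at 9.13 CPM, and highest in Tppp3 replicate 3, at 21.5. The cause was not tested. These rows were singled out after their values were seen.

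In the tests that follow, those on depth, on the near-constant reads, on pigment epithelium, on the vector's effect on every retina and on the oxidative phosphorylation list after correction were chosen after the result was seen. The 2 genes past the threshold were compared with the other splits of the 6 libraries into 3 and 3. There are 10 such splits, too few for a share under 0.05; the real one gave 2 genes, 3 splits gave at least as many with the real one included, and the highest other gave 175. That split set control replicate 1 and Tppp3 replicates 1 and 3, the libraries highest in pigment epithelium markers, against the rest, which points to a structure of the samples other than the vector.

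The first pattern was that ribosomal protein and oxidative phosphorylation genes were lower with Tppp3 AAV2. Sequencing depth follows the groups, and depth and an effect of the vector cannot be told apart: the deepest control lay at -0.0071 from the mean of the other controls in the ribosomal protein list (log2), while these differed from each other by 0.11. After thinning all libraries to the smallest total the median of that list was -0.11 and the list was still called with a preset correlation, but thinning keeps each gene's share of a library, so a trait of the libraries that goes with depth would remain and stays open. The transcripts of both lists are short, with a median length of 914 and 835 bases against 3220 for all tested genes, and a trend of libraries with transcript length and GC content may account for the oxidative phosphorylation part: after its removal the adjusted p was 0.616, as the median moved from -0.069 (quartiles -0.12 and 0.0026) to -0.0093 (quartiles -0.060 and 0.040). The ribosomal protein list still had an adjusted p of 2.3e-04 with a preset correlation, but its median moved from -0.10 (quartiles -0.15 and -0.074) to -0.047 (quartiles -0.075 and -0.011), and its unadjusted p with an estimated correlation was 0.137. The trend itself followed the groups. Deviations of each library correlated with transcript length at -0.063, -0.082 and -0.22 (Spearman) in control replicates 1, 2 and 3. In Tppp3 replicates 1, 2 and 3 the values were 0.13, 0.031 and 0.18. With GC content they were 0.072, 0.19 and 0.055 in the controls and -0.037, -0.031 and -0.24 with Tppp3 AAV2. The correction would also remove an effect of the vector along length or GC content. For both lists, therefore, the trend and an effect of the vector cannot be told apart.

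The second pattern was that more low-abundance genes were lower than higher with Tppp3 AAV2: of 8210 tested under a mean of 32 CPM, 87 were lower and 19 higher at an unadjusted p under 0.01, where 82.1 in all are expected by chance, and the 87 had a median log2 fold change of -0.47, while from 32 CPM up 73 were higher and 43 lower. The correction for GC content and length left that median at -0.45, so the fitted trend accounted for little of it. This cannot decide the cause. The 87 genes were picked by their p before correction, which favours large fold changes. Even the short ribosomal protein transcripts moved only from a median of -0.10 to -0.047 with this correction. The excess of lower genes was not counted again after it. For the excess itself such a trend stays open. A candidate explanation is a near-constant number of reads from another source in each library, which would weigh more in shallow libraries. In the 87 genes the deepest control had a median log2 ratio of -0.099 to the other controls. Only 0.19% of 10000 expression-matched random lists were that low or lower, although wholly constant reads would give -0.54 there. Depth follows the groups, so such reads and an effect of the vector cannot be told apart. The same limit holds for Krt7, Itgb4, Krt8, Spp1, Mcm2, Nsdhl, Tnfrsf12a, Emp1 and Tm4sf1, named above, which are among the 87 genes. A differing share of epithelial tissue stays open. Of 34 epithelial genes, 28 were negative with a median of -0.43, but 8 of the 34 are among the 87. Of the 26 outside, 20 were negative with a median of -0.20, and 0.1% of 10000 random lists were that low or lower. The epithelial genes were picked with the values known, so this comparison cannot decide, and the corneal list fixed in advance was not called.

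The third pattern was that pigment epithelium markers were higher with Tppp3 AAV2. Pigment epithelium carried over at dissection in some libraries of both groups may account for it, as control replicate 1 lay 2.23 above the mean of the other controls in the list mean (log2). Its abundant transcripts moved together: Ttr stood at 83.4, 28.1 and 32.7 CPM in control replicates 1, 2 and 3 and at 94.6, 35.99 and 87.2 in Tppp3 replicates 1, 2 and 3, and Rpe65 at 19.4, 1.23 and 1.36 and at 14.2, 2.12 and 17.0. Of the list's 16 tested genes, Krt18, Rrh, Mitf and Slc45a2 did not follow this division of the libraries. The highest control library lay 1.55 above the lowest Tppp3 library, but this sets a single library against another and excludes nothing, so carried-over tissue and an effect of the vector on every treated retina, or in some of them, cannot be told apart.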
